A study of Mus musculus with 8 samples.

How the data were processed

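The series holds 8 RNA-seq libraries of mouse bone marrow plasma cells, 4 from Control mice with loxP-flanked Taci alleles and 4 from mice that also carried Jchain-CreERT2 (cKO). CreERT2 is a Cre recombinase fused to a mutated estrogen receptor domain, which enters the nucleus when tamoxifen is bound. Groups and replicate numbers were taken from the sample titles. The series text speaks of triplicates, while 4 libraries per group were given and all were used.

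Per the labels' protocols, total RNA of 10000 sorted cells was reverse transcribed and amplified by PCR with a whole-transcriptome kit, and libraries were made from the amplified cDNA with a transposase-based kit. Such low-input amplification can lose rare transcripts at random and adds spread between libraries, above all for genes with low counts. The labels mention no molecular identifiers, so counts include PCR copies, and any precision derived from counts alone covers counting error only. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.7, aligned with STAR to GRCm38 and counted with featureCounts 2.0.1. The STAR version, the gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Overlapping or antisense genes and close paralogs may therefore share reads.

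The authors deposited raw counts per gene symbol, whole numbers that are not normalized, for 54880 symbols and 8 libraries. Total counts per library were 4922404, 4971022, 7412646 and 6334091 in Control 1 to 4 and 6300424, 5831399, 8482618 and 6007840 in cKO 1 to 4. Most immunoglobulin genes were not analysed here, and the planned shares of immunoglobulin constant genes and segments were therefore replaced by the share of Jchain. Shares are taken of the counts analysed here, a total that leaves out most immunoglobulin genes. Symbols were joined to GENCODE M21 (GRCm38) for gene identifiers, coordinates and the length and GC content of the longest transcript, and 52778 of 54880 symbols matched 1 gene. Libraries of a group were compared in pairs by a chi-square of their counts, which lay between 30.9 and 93.7 per degree of freedom, so no pair of libraries agreed within sampling noise. The genes Ddx3y, Eif2s3y, Kdm5d and Uty of the Y chromosome had at most 1 count in a library.

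CPM values, fold changes and tests were computed from these counts in R 4.3.3. Genes were filtered with filterByExpr by group (count minimum 10, total minimum 15), library sizes were scaled by TMM, and the groups were compared with edgeR 4.0.16 (glmQLFit with robust estimation, then glmQLFTest, without covariates). P-values were adjusted by the Benjamini-Hochberg method over all 10919 genes tested, with a threshold of 0.05. CPM values use the TMM-scaled library size. Values are given as mean ± SD over 4 libraries, and log2 fold changes with their standard error. Single values such as shares of counts were compared by two-sided exact permutation tests over 70 assignments, where the smallest possible p is 0.0286.

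There were 32 gene lists, fixed before the data were examined, for pathways, for plasma cell functions and for markers of other bone marrow cells. Of these 31 could be tested by camera (limma 3.58.1) on the same fit with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. The alternatives for lists were an estimated correlation and fry, whose directional test asks whether the members move on balance in a common direction and whose mixed test asks whether they change in either direction. With an estimated correlation many lists share an adjusted p of 0.429, which the adjustment gave to unadjusted camera p from 0.0642 to 0.235. The p also rose where the estimate lay next to the preset. For the ATF4 list, with an estimate of 0.0105, the unadjusted camera p went from 0.0323 to 0.0770. A call lost under this setting is therefore not by itself a sign that members move together. The list of immunoglobulin constant genes held Jchain alone and was not tested. Members were also adjusted over their list alone, which does not correct for the number of lists. A member that passes there is not a call over all genes.

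Genes named in the text were chosen by a rule set before the data were examined. It took Tnfrsf13b and Jchain, then up to 12 genes per direction past the threshold, or 5 per direction by smallest p where fewer than 5 passed. It left out receptor segments, pseudogenes, unnamed models and genes with a mean log2 CPM under 2. For each list called by camera it took the 4 members with the smallest p, and for other lists the 2 most abundant members. The text names part of these. Genes named outside the rule are said to have been chosen after their values were seen.

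The alternatives set beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom with sample quality weights, a fit that was not robust, glmTreat against a fold change of 1.5, no filter on low counts, and a filter of 1 CPM in 4 libraries. Further ones were the removal of immunoglobulin genes, the replicate number as a block, and each library left out in turn. The removal, which took out Jchain, left 10917 genes tested, against 10919 in the main analysis. Added after seeing the data were the newer quasi-likelihood estimate of edgeR, a filter at a mean log2 CPM of at least 5, and an unadjusted p for the genes near Jchain.

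The scripts were tested on simulated counts with the means, spread and library sizes of these data and 200 genes changed by known folds, of which 185 passed the filter. Of genes changed 2-fold, 4-fold, 8-fold and 16-fold, 6.52%, 45.7%, 53.2% and 58.7% were called, and 1 unchanged gene was called among 10221 tested. Fitted and true log2 fold changes correlated with r = 0.959 across changed genes, which are not independent replicates. A list shifted by −1 on the log2 scale was called by camera (adjusted p = 2.81e-18). In counts simulated without any change 4.27% of genes had a p under 0.05, 1 gene was called and 0 lists were. The simulated genes vary independently of each other. The simulation therefore cannot show how camera behaves for lists whose members move together, as in the real libraries.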

Results

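RNA was profiled from plasma cells of mouse bone marrow, the long-lived antibody-secreting cells, sorted by high CD138 and absence of B220. All mice carried loxP-flanked alleles of Taci, the gene whose symbol in the count table is Tnfrsf13b. It encodes TACI, a receptor for the survival cytokines BAFF and APRIL. The 4 cKO libraries came from mice that also carried a tamoxifen-inducible Cre recombinase at the Jchain locus, and the 4 Control libraries from mice without it. Both genotypes were given tamoxifen at 100 mg per kg on 3 days, and each library was made from 10000 cells. The libraries held between 4922404 counts (Control 1) and 8482618 counts (cKO 3), over 11599 to 16521 genes with at least 1 count. Control 3 stood apart from the rest. Its median correlation of log2 CPM with the other libraries was 0.746, against 0.805 to 0.856 for the other 7. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may in part be technical.

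The comparison asked what plasma cells express after deletion of Taci, and the targeted gene was examined first. Tnfrsf13b (ENSMUSG00000010142.12, GRCm38 chromosome 11, 61126755 to 61149372, plus strand) fell in cKO, from 715 ± 204 CPM in Control to 64.0 ± 26.1 CPM (SD, n = 4 in each group). The remaining level was 8.95% of Control. Raw counts were 3646, 3010, 3124 and 5597 in Control 1 to 4, and 676, 468, 561 and 175 in cKO 1 to 4. In this gene every library matched its label. Esr1, described below, set Control 1 apart from the other Control libraries. The log2 fold change was −3.48 (SE 0.35), with an adjusted p of 0.00743 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test of log2 CPM gave p = 0.0286, the smallest that 4 against 4 libraries allow. With cKO 2 or cKO 3 left out, the fold changes were −3.57 and −3.45 and the adjusted p by the same edgeR test 0.0668 and 0.0952. The exons deleted by Cre are not given in the sources used here, so counts from the remaining exons may be part of the cKO level.

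**Figure D1:**
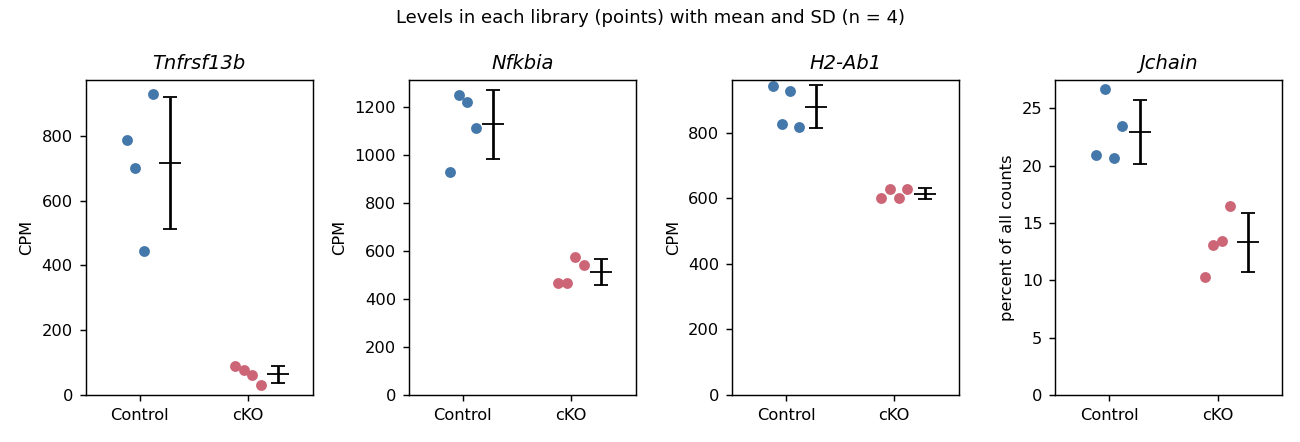
Levels of Tnfrsf13b, Nfkbia and H2-Ab1 in CPM, and of Jchain in percent of all counts analysed here, in the Control and cKO libraries. Points are libraries and bars the mean and SD (n = 4). For each gene all 4 cKO libraries lie below all 4 Control libraries, at 64.0 against 715 CPM on average for Tnfrsf13b.

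Beyond the targeted gene, no difference passed the edgeR test in the main analysis. Of 10919 genes tested by edgeR's quasi-likelihood test, 1 passed an adjusted p of 0.05 (Tnfrsf13b, lower) and 0 were higher. At an unadjusted p under 0.05 there were 142 higher and 144 lower genes, together 2.62% of those tested. In counts simulated without any change the share was larger, at 4.27%. The same threshold was passed by 286 genes here, 427 with DESeq2 and 458 with limma voom. With the newer edgeR estimate, added after seeing the data, it was passed by 620. DESeq2 called 5 higher and 9 lower genes, and limma voom with quality weights 0 higher and 3 lower. Leaving out Control 1 gave 3 genes, which added Nfkbia (lower, adjusted p = 0.0425) and Esr1 (higher, adjusted p = 0.0417), the estrogen receptor gene, chosen after its value was seen. Leaving out cKO 2 or cKO 3 gave 0. The groups did not overlap for 346 genes (3.17%), where chance gives 2.86%. The biological coefficient of variation between libraries was 0.721. In data simulated with the means and spread of these libraries, the same test called 6.52% of genes changed 2-fold and 45.7% of those changed 4-fold.

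The genes next in rank after Tnfrsf13b among those lower did not pass the edgeR test and are given as values. Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647, minus strand), which encodes the NF-kB inhibitor IkBα and is itself an NF-kB target, stood at 1129 ± 146 CPM in Control and 513 ± 55.3 CPM in cKO (SD, n = 4). Its log2 fold change was −1.14 (SE 0.16), with an adjusted p of 0.0733 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It passed with DESeq2 (adjusted p = 3.35e-09) and with limma voom (adjusted p = 0.00405). Il2rg, the common gamma chain of several interleukin receptors, had a log2 fold change of −1.04 (SE 0.19), from 303.9 ± 52.3 to 148 ± 18.4 CPM. Ccr10, a chemokine receptor of IgA-producing plasma cells, had −1.59 (SE 0.34), from 216 ± 84.5 to 71.4 ± 24.0 CPM. The groups did not overlap for Nfkbia and Il2rg and overlapped for Ccr10. DESeq2 called both Il2rg (adjusted p = 0.00116) and Ccr10 (adjusted p = 0.00506).

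The highest-ranked genes in the other direction did not pass the edgeR test either, although for each all 4 cKO libraries lay above all 4 Control libraries. Sc5d, an enzyme of late cholesterol synthesis, had a log2 fold change of 1.51 (SE 0.29), from 24.7 ± 2.86 to 70.4 ± 14.9 CPM. Adk, adenosine kinase, had 1.06 (SE 0.21), from 294 ± 77.1 to 614 ± 83.6 CPM. DESeq2 called Sc5d (adjusted p = 0.00317) and Adk (adjusted p = 0.00506). Aldh6a1, a mitochondrial enzyme of valine breakdown, had 2.09 (SE 0.51), Tmem127 1.67 (SE 0.42), and Neu1, the lysosomal sialidase, 1.05 (SE 0.26).

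NF-kB target genes, which include the subunits and inhibitors of NF-kB itself, fell as a group in cKO. Of the 29 genes on the list 26 were tested, of which 20 had a negative and 6 a positive log2 fold change, with a median of −0.84. The list was called by camera with a preset correlation (adjusted p = 1.55e-06), and the adjusted p was 0.0589 with an estimated correlation. The estimate was 0.0099, next to the preset 0.01, so the larger p does not come from members moving together. Nfkbia was the only member that passed when adjusted over the list alone (adjusted p = 0.000349, edgeR's quasi-likelihood test), and 0 members passed over all genes tested. The other members that the naming rule took were Icam1, an adhesion molecule, at −1.46 (SE 0.45), Nfkb2, the p100 subunit of the alternative pathway, at −1.57 (SE 0.50), and Tnip1, a partner of the inhibitor A20, at −1.28 (SE 0.45). For Nfkb2 the cKO libraries, at 25.6 ± 16.01 CPM, lay below every Control library, which averaged 76.5 ± 31.6 CPM (SD, n = 4). Some further members were chosen after their values were seen. Nfkb1 stood at −1.21 (SE 0.56), Relb at −1.22 (SE 0.58), Nfkbib at −0.68 (SE 0.28) and Tnfaip3, which encodes A20, at −0.86 (SE 0.42). The negative values did not extend to every member. The well-expressed members Gadd45b (−0.02, SE 0.21), Ier5 (0.12, SE 0.18) and Sod2 (0.29, SE 0.24) had values near or above 0. Over the 12 members with a mean log2 CPM of at least 5 the median was −0.50. Leaving out any library in turn kept the call, with adjusted p up to 3.05e-04 by camera.

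**Figure D2:**
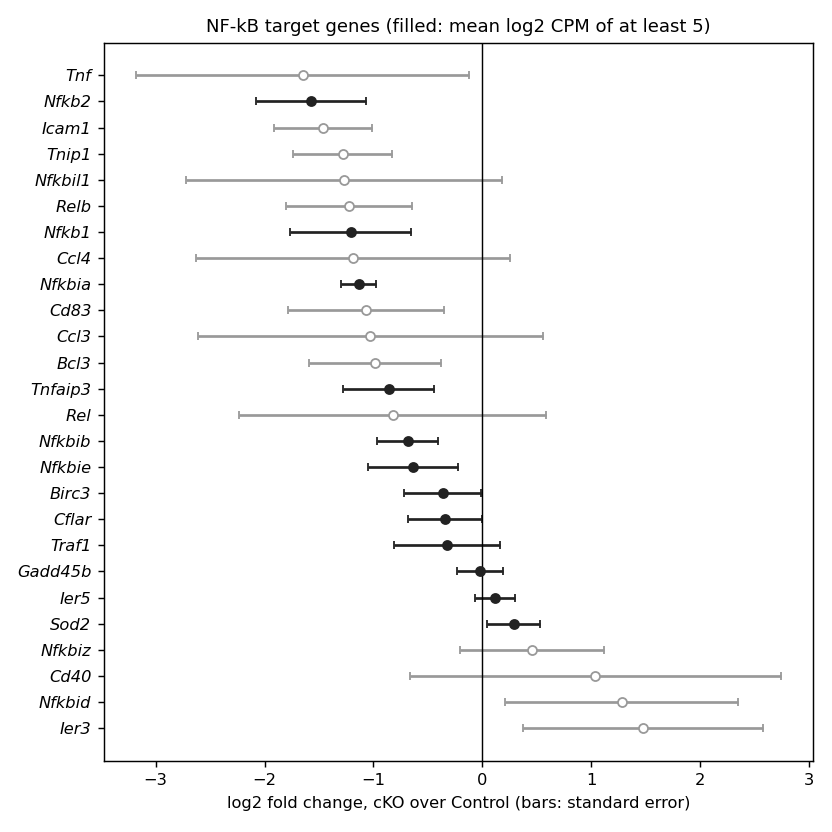
Log2 fold change of cKO over Control (x axis) for each tested NF-kB target gene (y axis), with its standard error; filled points have a mean log2 CPM of at least 5. Of 26 genes 20 lie below 0, with Nfkbia at −1.14 the most precise of them, while Gadd45b, Ier5 and Sod2 lie between −0.02 and 0.29.

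The remaining receptors of the same cytokine system did not follow Tnfrsf13b. Tnfrsf17, which encodes BCMA, the receptor on which plasma cell survival depends, stood at 282 ± 72.6 CPM in Control and 313 ± 52.2 CPM in cKO (log2 fold change 0.15, SE 0.22). Tnfrsf13c, the BAFF receptor gene, stood at 181 ± 50.6 and 233 ± 56.4 CPM (0.37, SE 0.26). Across 12 tested BAFF and APRIL receptors, ligands and adaptors the median log2 fold change was 0.12 (camera adjusted p = 0.475). Birc2, an adaptor of that list chosen after its value was seen, had 0.66 (SE 0.29). The 4 tested pro-survival BCL2 family genes had a median of −0.48 (camera adjusted p = 0.0834). The list passed without Control 1 (0.01004) and without cKO 1 (0.0124). The adjusted p was 0.429 with an estimated correlation. Among them, Mcl1, the BCL2 relative that plasma cells need, had −0.46 (SE 0.29), and Bcl2 −0.50 (SE 0.39). With a library left out these values ranged from −0.72 to −0.25 for Mcl1 and from −0.87 to −0.23 for Bcl2. For 18 pro-apoptotic BCL2 family and caspase genes the median was −0.15 (camera adjusted p = 0.688).

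The lists of the plasma cell programme did not pass camera in the main analysis. The 25 plasma cell identity genes had 12 positive and 13 negative log2 fold changes, with a median of −0.03 (camera adjusted p = 0.923). Xbp1, the transcription factor of the secretory programme, stood at 8439 ± 997 CPM in Control and 8498 ± 957 CPM in cKO (SD, n = 4), a log2 fold change of 0.01 (SE 0.14) that turned negative with RLE (−0.0024) or upper-quartile (−0.017) scaling. Edem1, which clears misfolded proteins from the endoplasmic reticulum, stood at 0.20 (SE 0.14). The 38 genes of the XBP1 and ATF6 unfolded protein response had a median of 0.10 (camera adjusted p = 0.611), and the 38 genes of the secretory pathway and N-glycosylation 0.12 (adjusted p = 0.393). The 24 ATF4 integrated stress response genes had a median of 0.18 (adjusted p = 0.0834), with Slc3a2, an amino acid transporter subunit, at 0.19 (SE 0.24). This list passed as higher at a mean log2 CPM of at least 5 (0.0186), without a filter on low counts (0.0466) and without Control 1 (0.0457), and its adjusted p was 0.429 with an estimated correlation.

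Jchain, which encodes the chain that joins IgM and IgA into polymers, took a smaller share of the counts in cKO. Of the counts analysed here, which leave out most immunoglobulin genes, its share was 22.9% ± 2.79 in Control and 13.3% ± 2.56 in cKO (SD, n = 4). The groups did not overlap. An exact permutation test gave p = 0.0286, the smallest possible, and 0.0857 after Benjamini-Hochberg adjustment over 6 shares. The log2 fold change of Jchain (ENSMUSG00000067149.6, chromosome 5, 88519809 to 88527891, minus strand) was −0.99 (SE 0.20), with an adjusted p of 0.608 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 (adjusted p = 0.00317) and limma voom (adjusted p = 0.0265) called it. By the labels the cKO mice carried the Cre allele at this locus and the Control mice did not. The loss of Taci and the Cre allele therefore cannot be told apart for this gene. Of the 14 immunoglobulin constant genes and Jchain on one list only Jchain was tested, and the other members were not analysed here. The 10 most abundant genes took 34.0% ± 3.15 of the counts in Control and 24.8% ± 3.83 in cKO (exact permutation p = 0.0286, and 0.0857 adjusted over the 6 shares). Without Jchain these values were 15.04% ± 1.43 and 13.9% ± 2.58 (exact permutation p = 0.486).

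Genes of ribosomal proteins, of respiration and of the proteasome were lower as groups by camera with a preset correlation. The test that allows for their common movement did not call them. For 76 cytosolic ribosomal protein genes the median log2 fold change was −0.36, and 75 were negative (adjusted p = 7.71e-15). Rpsa stood at −0.66 (SE 0.26) and Rplp2 at −0.66 (SE 0.31). For 75 oxidative phosphorylation genes the median was −0.29, and 65 were negative (adjusted p = 1.68e-08). Among them were the complex I genes Ndufa2 at −0.67 (SE 0.24), Ndufa4 at −0.68 (SE 0.27) and Ndufs7 at −0.51 (SE 0.22), and the complex IV gene Cox6b1 at −0.42 (SE 0.19). For 34 proteasome genes the median was −0.12, and 25 were negative (adjusted p = 0.0274), with Psmb6 at −0.46 (SE 0.20) and Psmb8 at −0.41 (SE 0.18). With an estimated correlation the adjusted p was 0.429 for each of these lists. The ribosomal protein and oxidative phosphorylation lists moved with Control 3, where ribosomal protein genes took 3.06% of the counts, against 1.72% to 2.32% in the other libraries. As a share of all counts analysed here, ribosomal protein genes took 2.21% ± 0.631 in Control and 2.04% ± 0.170 in cKO (SD, n = 4, exact permutation p = 0.771). Control 1 (1.74%) and Control 4 (1.72%) lay below every cKO library. Without Jchain in the total the shares were 2.87% ± 0.795 and 2.36% ± 0.227 (exact permutation p = 0.343). Control 1 (2.20%) and Control 4 (2.25%) then lay above the lowest cKO library (cKO 3, 2.14%). Without Control 3 the median was −0.16 for ribosomal proteins and −0.10 for oxidative phosphorylation. The proteasome call was lost without Control 2, Control 4, cKO 1, cKO 2 or cKO 3, with adjusted p from 0.0524 to 0.106.

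Cell cycle genes were the only list that rose by camera with a preset correlation, with 28 of 36 genes positive and a median of 0.24 (adjusted p = 0.0274). The adjusted p was 0.429 with an estimated correlation. Ccna2, cyclin A2, stood at 1.34 (SE 0.42), from 22.6 ± 10.5 to 57.3 ± 9.68 CPM, and Nusap1, a spindle protein, at 1.00 (SE 0.36), both without overlap between groups (n = 4). Mcm7, a subunit of the replicative helicase, stood at 0.93 (SE 0.38). The call was lost without Control 2, Control 3, Control 4, cKO 1 or cKO 2, with adjusted p from 0.0549 to 0.199. Erythroid and B cell progenitor markers, from bone marrow cells that divide, had positive medians too, which did not pass camera in the main analysis. The medians were 0.50 for erythroid markers (11 of 14 positive, adjusted p = 0.0705) and 0.77 for B cell progenitor markers (6 of 7 positive, adjusted p = 0.0834). Neutrophil markers had a negative median of −0.21 (13 of 18 negative, camera adjusted p = 0.148). The 2 well-detected B cell progenitor markers had a median of −0.18, so the positive median came from members with low counts. The erythroid list passed at a mean log2 CPM of at least 5 (0.0279), without a filter on low counts (0.0155) and without cKO 4 (0.02097), and the B cell progenitor list without a filter (0.03496) and without Control 3 (0.00592). With an estimated correlation the adjusted p was 0.429 for both.

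Of 11 tested genes of antigen presentation by MHC class II, 8 had a negative and 3 a positive log2 fold change. H2-Ab1, which encodes the beta chain of the class II molecule I-A, stood at 878 ± 65.7 CPM in Control and 614 ± 15.9 CPM in cKO (log2 fold change −0.52, SE 0.14; n = 4). Cd74, the invariant chain, had a log2 fold change of −0.47 (SE 0.13), and for both the groups did not overlap. H2-Aa, chosen after its value was seen, had −0.83 (SE 0.36), with overlapping groups and 104 ± 51.9 CPM in Control. With a library left out the value of H2-Aa ranged from −1.04 to −0.43. Over all genes 0 members passed, and H2-Ab1 and Cd74 passed when adjusted over the list alone (both adjusted p = 0.0224, edgeR's quasi-likelihood test). The list did not pass camera (adjusted p = 0.0538), and the adjusted p was 0.429 with an estimated correlation. With all 8 libraries it passed with limma voom (0.00351) and at a mean log2 CPM of at least 5 (0.00791). With a library left out its adjusted p ranged from 0.00592 (without Control 3) to 0.37 (without Control 1), and it also passed without cKO 3 (0.0214).

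The other metabolic and signalling lists did not pass camera in the main analysis. The median log2 fold change was 0.13 for 17 glycolysis genes (adjusted p = 0.419), 0.28 for 22 cholesterol synthesis genes (0.148) and 0.22 for 24 autophagy genes (0.104). Cholesterol synthesis passed as higher at a mean log2 CPM of at least 5 (0.0255), autophagy without a filter on low counts (0.03496) and without Control 1 (0.0386), and glycolysis without Control 1 (0.0386). With an estimated correlation 0 lists passed. Of the cholesterol synthesis genes Sc5d passed when adjusted over the list alone. Sqstm1, a cargo receptor of autophagy, stood at 0.27 (SE 0.23). The median was 0.17 for 21 p53 target genes (camera adjusted p = 0.226), where Trp53inp1 had 0.53 (SE 0.17) and Btg2 0.34 (SE 0.19). It was 0.14 for 35 interferon-stimulated genes (0.419). The most abundant of these went the other way, with Ly6a, a surface antigen, at −0.38 (SE 0.13) and Isg20, an RNA exonuclease, at −0.32 (SE 0.17), neither overlapping between groups. For 27 migration and adhesion genes the median was 0.23 (0.226), and Ccr10 passed when adjusted over the list alone. Immediate early and heat shock genes had a median of 0.24 over 19 genes (0.259), with Fos at 0.24 (SE 0.21). The 7 tested mitochondrially encoded transcripts had a median of −0.11 (0.44), and passed as lower without Control 1 (0.0434).

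**Figure D3:**
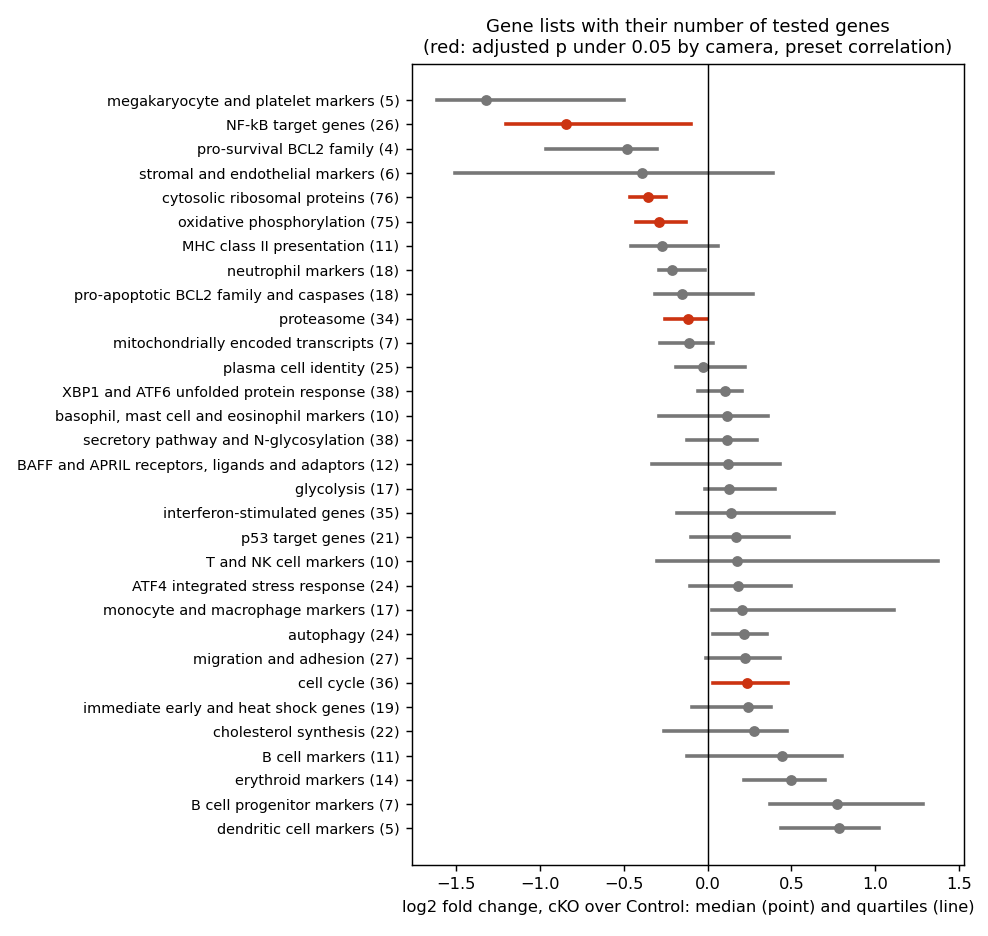
Median log2 fold change of cKO over Control (point) and quartiles (line) for the 31 tested gene lists, with the number of tested genes in brackets; red marks an adjusted p under 0.05 by camera with the preset correlation. The NF-kB list, at a median of −0.84, lies farthest from 0 of the 5 lists in red.

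Transcripts of other bone marrow cells were present in all libraries. Neutrophil markers took 4.46% ± 1.68 of the counts in Control and 4.24% ± 0.753 in cKO (SD, n = 4, exact permutation p = 0.914). Without Jchain in the total these shares were 5.79% ± 2.12 and 4.91% ± 0.921 (exact permutation p = 0.486). The neutrophil list had a median log2 fold change of −0.21 over 18 genes (camera adjusted p = 0.148). Camera called this list lower without Control 3 (0.00592), Control 4 (0.0398) or cKO 2 (0.0294), and placed it higher without Control 1 (0.438). The adjusted p was 0.764 with all libraries and an estimated correlation. S100a8, an abundant neutrophil granule gene, stood at −0.33 (SE 0.29). The median was 0.21 for 17 monocyte and macrophage markers (adjusted p = 0.148), 0.45 for 11 B cell markers (0.0705) and 0.77 for 7 B cell progenitor markers (0.0834), of which the 2 well-detected ones had −0.18. Cd79b of the B cell receptor stood at 0.18 (SE 0.17) and Vpreb3 at −0.59 (SE 0.36). The median was 0.18 for 10 T and NK cell markers (0.226) and 0.50 for 14 erythroid markers (0.0705), with Car2 at 0.58 (SE 0.44) and Hba-a1 at 0.45 (SE 0.41). It was −1.32 for 5 megakaryocyte and platelet markers (0.0538), all with low counts. Of these Itgb3, at −2.59 (SE 0.79), passed when adjusted over the list alone. Its groups overlapped, and its adjusted p over all genes was 0.9996 by edgeR's quasi-likelihood test. The median was 0.11 for 10 basophil, mast cell and eosinophil markers, which camera placed lower (0.392), with Prg2 at −0.54 (SE 0.20). It was −0.39 for 6 stromal and endothelial markers (0.314). Without a filter on low counts the B cell (0.0132), T and NK cell (0.0182) and monocyte and macrophage (0.03496) markers passed as higher, the last also without Control 1 (0.0186). The megakaryocyte markers passed as lower without Control 2 (0.0138), and the stromal markers without Control 1 (0.0386) or cKO 4 (0.0394). For 5 dendritic cell markers the median was 0.79 (0.868), but the most abundant of them, Ly6d, which B-lineage cells also express, had −0.996 (SE 0.22), from 2454 ± 756 to 1230 ± 236 CPM without overlap. Ly6d passed when adjusted over the list alone and with DESeq2 (adjusted p = 0.00983).

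Genes around Jchain were examined because by the labels only the cKO mice carried an altered Jchain allele. Of 39 tested genes within 10 Mb of Jchain 0 passed the adjusted p of edgeR's quasi-likelihood test, against 1 of 10722 elsewhere (two-sided Fisher's exact p = 1). With a single gene past the threshold this test could not find a difference. At an unadjusted p under 0.05, a threshold chosen after seeing the data, 3 of 39 genes near Jchain and 275 of 10722 others passed (Fisher's exact p = 0.0789). Within 20 Mb there were 7 of 122 genes against 271 of 10639 (Fisher's exact p = 0.0387). Jchain itself, the altered gene, is counted among the genes near it that passed the unadjusted threshold.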

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

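The tests of the neutrophil, monocyte and mislabelling explanations and of the Cre-ERT2 reads, and the trends with length or GC content alone, were chosen after the results were seen; the counts of splits and the tests for the joint trend were set before their results were seen.

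Among 138 groups of 4 values, 5 held a library whose gap to the nearest other passed the 95% critical value of Dixon's test for an outlier, where chance gives about 1 in 20 such groups. Icam1 stood at 15.03 CPM in Control 3, against 52.4 to 59.4 CPM in the other Control libraries. Mcm7 stood at 53.7 CPM in Control 4, against 18.8 to 23.5 CPM in the others. Ccr10 stood at 107 CPM in cKO 3, against 55.5 to 63.9 CPM. Mcl1 stood at 323 CPM in cKO 1, against 171 to 192 CPM. Esr1, chosen after its values were seen, had 98 counts in Control 1, against 0, 1 and 0 in Control 2 to 4.

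Esr1, the estrogen receptor gene (chromosome 10, 4611593 to 5005614), had 186, 116, 228 and 146 counts in cKO 1 to 4, so that Control 1 resembled the cKO libraries in this gene. A swap of Control 1 with a cKO library is argued against by its levels of Tnfrsf13b and Jchain. Tnfrsf13b stood at 787 CPM in Control 1 and at most 90.5 CPM in cKO. The Jchain share of Control 1 was 20.9%, above the highest cKO share of 16.5%. These values cannot show whether Control 1 carried CreERT2 without deletion of Taci. The estrogen receptor domain of CreERT2 may give reads that align to Esr1, which is a candidate explanation for the cKO counts. It gives the 98 counts of Control 1 no source if the label of that library is right about CreERT2. Control 1 stood at 21.15 CPM of Esr1, within the 18.8 to 24.9 CPM of the cKO libraries. Counts per gene cannot show which part of Esr1 the reads cover. Expression of the native gene in some of the sorted cells stays open as well and was not tested.

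Of the 35 splits of the 8 libraries into 4 and 4, only the real split (1 of 35) gave the NF-kB target genes a camera p as small (1.5e-07, against 7.25e-05 for the smallest of the others). That is the smallest share these splits can give, for 1 of 31 lists, and the adjusted p of 0.0589 with an estimated correlation leaves some room for chance. Fewer neutrophils in the cKO sort, which should exclude them, are argued against as the whole cause by a median of −0.21 over 18 markers (S100a8 at −0.33 and Ngp at −0.25, and no lower than −0.50 and −0.40 with a library left out), and with a neutrophil score as covariate the NF-kB median went from −0.84 to −0.68 (camera adjusted p = 3.7e-06). Fewer monocytes or macrophages are argued against as the whole cause by a median of 0.21 over 17 markers, of which the 3 well-detected ones had 0.089 and Lyz2 −0.31; with their score as covariate the NF-kB median was −0.57 (adjusted p = 1.13e-04), so a part of the shift may go with either cell type. A trend with transcript length, GC content or expression level left a median of −0.86 once removed (−0.87 with GC content alone), below all of 10000 random lists matched on expression. Fewer cells of other types in the cKO sort were not tested as a cause. The 5 megakaryocyte and platelet markers, all with low counts, had a median of −1.32. The 6 stromal and endothelial markers had −0.39, and the other untested lists of marrow cell markers had positive medians. Lower NF-kB output in plasma cells of the cKO mice is a hypothesis, since TACI is known to signal to NF-kB. The design cannot separate loss of Taci from the presence of the Cre recombinase, which by the labels only the cKO mice carried. Plasma cells of tamoxifen-treated Jchain-CreERT2 mice without loxP-flanked Taci would be the test of this hypothesis, and are not in this series.

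The lower cytosolic ribosomal protein genes differed in this respect. As many as 8 of the 35 splits gave a camera p as small as the real 2.49e-16, the smallest being 1.05e-36, so chance cannot be excluded. That split set Control 1, Control 4, cKO 1 and cKO 3 against the rest, which points to a structure among the libraries that crosses the genotypes. Removing a trend with transcript length, GC content and expression level took the median from −0.36 to −0.19. It was −0.22 with length alone and −0.36 with GC content alone. The −0.19 lay below all of 10000 random lists, but those were drawn gene by gene. Ribosomal protein genes move together (estimated correlation 0.71), so the random lists cannot tell what remains from chance. The fitted trend took away part of the shift, and the cause of the rest is not decided. A biological effect of the genotype on these genes stays open and was not separated from this structure.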

How the results depend on the processing

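Values under the newer edgeR estimate, the filter at a mean log2 CPM of at least 5 and the unadjusted p were chosen after seeing the data; where a call or count moved and no reason is given, the cause was not tested. The count of changed genes (1) was 14 with DESeq2 (5 higher, 9 lower), 3 with limma voom (all lower), 12 without a filter on low counts (3 higher, 9 lower), 2 with the newer edgeR estimate and 2 at a mean log2 CPM of at least 5 (lower in both). Leaving out each library gave 0 to 3 genes, with 0 to 1 higher and 0 to 2 lower. The log2 fold change of Tnfrsf13b lay between −3.70 and −3.24 over these, with adjusted p up to 0.0952 by edgeR's quasi-likelihood test. The labels do not say that the replicate numbers pair the samples. Same-numbered libraries correlated at −0.23, 0.05, −0.09 and 0.05 in their deviations from the group means, and other pairs at −0.16 to 0.31. So few values cannot show whether the numbers mark a shared batch. With the number as a block 0 genes were called (0 lower), Tnfrsf13b had −3.52 (adjusted p = 0.165), and the proteasome median was −0.11 (adjusted p = 0.0508).

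The count of called lists (5) was 12 without a filter on low counts, 9 at a mean log2 CPM of at least 5, 0 with an estimated correlation, 0 with directional and 1 with mixed fry (the NF-kB list), and 4 to 12 with a library left out, the 12 without Control 1. The adjusted p of the NF-kB list (median −0.84) was 0.0768 with directional fry, and under the other camera settings with the preset correlation and all 8 libraries it lay between 9.28e-07 and 8.69e-06. With directional and mixed fry the adjusted p was 0.428 and 0.497 for oxidative phosphorylation (−0.29), 0.304 and 0.497 for the cell cycle (0.24), 0.304 and 0.497 for the proteasome (−0.12), and 0.433 and 0.497 for ribosomal proteins (−0.36). With a library left out the medians lay between −0.96 and −0.67 for NF-kB targets, −0.36 and −0.10 for oxidative phosphorylation, −0.46 and −0.16 for ribosomal proteins, −0.16 and −0.074 for the proteasome, and 0.18 and 0.39 for the cell cycle.

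Of 1132 values of 60 named genes under alternatives, 1097 kept their direction and side of the threshold, 22 passed it and 13 changed sign, in 4 genes. Of these Ngp (−0.25) and Lyz2 (−0.31) changed sign without Control 1, and Xbp1 and Gadd45b lay near 0. Xbp1 was −0.0024 with RLE scaling and with DESeq2, −0.017 with upper-quartile scaling, −0.052 with limma voom, and −0.052 to 0.085 with a library left out. The leave-one-out ranges were −0.40 to 0.055 for Ngp, −0.54 to 0.0029 for Lyz2 and −0.092 to 0.056 for Gadd45b. The difference in the Jchain share lay between −10.7 and −8.37 percentage points with a library left out. Fisher's exact p for genes near Jchain, with Jchain itself counted among them, was 0.0488 at 5 Mb and 0.0387 at 20 Mb with an unadjusted p. The spread between libraries limits what the test can call, since in counts simulated with it 6.52% of 2-fold changes were called. At an unadjusted p under 0.05 the share of genes was 4.27% in counts simulated without change and 2.62% in the real libraries. The simulated percentage may therefore not hold for the real libraries.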

Other observations

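Pim2 and Cyba were chosen after their values were seen, as was the unadjusted p for genes near Jchain. The test of genes off in a group was prompted by genes seen in the data, but its result was not seen beforehand.

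Pim2, a kinase that supports survival of plasma cells and a known NF-kB target absent from the fixed list, had a log2 fold change of −1.32 (SE 0.36), from 200.5 ± 86.9 CPM in Control to 80.2 ± 36.6 CPM in cKO (SD, n = 4). The groups did not overlap. It did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.9996). By the same test it passed without a filter on low counts (adjusted p = 0.00444). DESeq2, limma voom, the newer edgeR estimate and the filter at a mean log2 CPM of at least 5 did not call it. Without the low-count filter the adjusted p was far smaller for other genes too, as for Jchain (2.25e-16, against 0.608). Cyba, a subunit of the phagocyte NADPH oxidase, had −0.91 (SE 0.21), from 1597 ± 495 to 849 ± 82.1 CPM without overlap, and DESeq2 called it (adjusted p = 0.0211).

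Of the 35 splits of the libraries, 1 gave as many changed genes as the real split, which was the real split with 1 gene, and the highest of the others gave 0. Since 1 gene was also called in counts simulated without any change, this count leaves some room for chance. For Tnfrsf13b, named beforehand, the values themselves lie apart, with at least 443 CPM in every Control and at most 90.5 CPM in every cKO library. For the number of gene lists called by camera chance cannot be excluded, since 17 of 35 splits gave at least the real 5, and the highest of the others gave 11. The preset correlation therefore calls lists in splits that cross the genotypes. Of the other called lists, a camera p as small as the real one came from 6 of 35 splits for oxidative phosphorylation, 5 for the cell cycle and 4 for the proteasome.

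There were 8 genes with at least 20 counts in every cKO library and at most 10 in every Control library, and 0 of the opposite kind. Since 10 of 35 splits gave at least 8 such genes, up to 25, chance cannot be excluded for this pattern.

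Sequence linked to the Jchain allele may differ between the genotypes and could alter genes nearby. The test within 10 Mb gave a Fisher's exact p of 1, but with 1 changed gene in all it could not have found a difference, so strain sequence linked to the Jchain allele and loss of Taci cannot be told apart for genes of that region. At an unadjusted p under 0.05 the share of genes near Jchain was 3 of 39, against 275 of 10722 elsewhere (Fisher's exact p = 0.0789). It was 3 of 32 within 5 Mb (Fisher's exact p = 0.0488) and 7 of 122 within 20 Mb (Fisher's exact p = 0.0387). Each of these counts near Jchain holds Jchain itself (unadjusted p = 0.000334 by edgeR's quasi-likelihood test), the gene that carries the Cre allele. With Jchain among so few genes, these tests cannot show whether its neighbours differ from genes elsewhere.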
